A study of Mus musculus with 14 samples.

How the data were processed

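Chromatin immunoprecipitation followed by sequencing was carried out on mouse embryonic stem cells (mESCs) and on gastruloids, aggregates of these cells grown for 120 h. The 4 proteins were tagged at their own genes in the same E14 reporter line: p300 with V5, and RXRα, Sp5 and Zeb2 with HA. The labels describe the p300 tag as joined to miniTurboID and the HA tags as joined to an FKBP12 degron. Of the 14 libraries, 12 were immunoprecipitations, with 2 replicates for each of p300 and RXRα in mESCs and in gastruloids and for Sp5 and Zeb2 in gastruloids. The other 2 were inputs, 1 per cell type, both from the p300 line. Libraries were put in 8 groups by the cell type and antibody of their labels, and the replicate number came from the title.

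The deposited files held 1 list of peaks per library, not pooled between replicates, with 422096 peaks in total. Per the submitters' processing notes, the authors used fastp 0.20.1, BWA 2.2.1 and MACS2 2.2.7 with the mouse build GRCm38.p6, also given as mm10; the roles and order of these tools and the use of an input as control were not stated. The deposited score of each peak was a whole number equal to 10 times its −log10 q, rounded down. The authors' fold enrichment is a ratio of the signal at the summit to the local background, as MACS2 defines it. The authors gave each peak a −log10 p and a −log10 q, and the smallest −log10 q of the lists corresponded to a q threshold of 0.05. The last deposited column gave the position of the summit in base pairs from the start of the peak. All of these values are the authors' own, and they were compared only inside a list or between positions of the 2 replicates of a group.

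Peaks with the same start and end were counted once, with the strongest summit kept. Only peaks on the 21 main chromosomes were used, and peaks that overlapped a peak of either input were removed. A region of a group was a stretch covered by a peak in both replicates, with an overlap of at least 1 bp. For p300 and RXRα, a gastruloid-only region was found in both gastruloid libraries and overlapped no peak of either mESC library, an mESC-only region was the reverse, and a shared region was covered in all 4 libraries. Regions found in fewer libraries belonged to none of these classes. Reads and coverage tracks were not analysed here, so differences in height between cell types were not measured, and presence in a list stands in for binding.

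Sequencing depth was not given. The number of fragments at each summit and the local background were recovered from the deposited fold and −log10 p, and the pileups came out whole within 0.01 for nearly every peak. The lowest local background gave a fragment density of 11.4 and 9.83 per kb in the p300 mESC libraries, 7.82 and 7.13 in p300 gastruloids, 9.52 and 9.53 in RXRα mESCs, 7.08 and 6.66 in RXRα gastruloids, 5.54 and 7.84 for Sp5, and 6.11 and 5.50 for Zeb2. The inputs had 3.28 (mESCs) and 6.10 (gastruloids). The median peak held 15 to 40 fragments, so a peak of this size carries a counting error of roughly its square root, and weaker sites can be missed in 1 library by chance alone.

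Genes were the 21887 protein-coding genes of a RefSeq table of the same build. The table gives no strand, so the start of transcription could not be told from the other end of a gene. In place of the promoters planned before the data were examined, a region was put at a gene end when its summit lay within 1 kb of either end of a gene. Each region was assigned to the gene with the nearest end within 100 kb of the summit. Nearness does not show which gene a region regulates.

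The comparisons were of 4 kinds. Shares of regions at gene ends were compared between classes by Fisher's exact test, two-sided, and given for each replicate alone. The overlap of RXRα, Sp5 and Zeb2 regions with p300 regions was compared by permutation with 1000 placements of the same regions at random on their own chromosomes, one-sided, for which the smallest p possible is 0.000999. Pairs of factors at p300 regions were compared by odds ratios with 95% intervals and Fisher's exact test, two-sided, adjusted over the 3 pairs. Gene lists were compared by a permutation test with 10000 random lists of genes matched on the number of regions in 8 bins, two-sided, with p adjusted by Benjamini and Hochberg over the 16 lists and a threshold of 0.05; the smallest p that these draws can give is 0.0002. With 2 libraries against 2 an exact test on libraries cannot fall under 0.333, so none was used as evidence.

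The 16 lists were fixed before the data were examined: naive and general pluripotency, primitive streak and tail bud, presomitic mesoderm and somites, neural tube, neural crest, endoderm and notochord, cardiac and lateral plate mesoderm, endothelium and blood, Hox genes, Wnt pathway targets, retinoic acid signalling, lipid nuclear receptor targets, epithelial identity and EMT, BMP and TGF-beta feedback, trophoblast, and an adult tissue control. They held 313 genes with 321 memberships, all of which were found in the gene table. The epithelial identity and EMT list, epithelial for short, also held genes of mesenchymal cells and EMT. These were Cdh2, Vim, Fn1, Snai1, Twist1, Zeb1 and Zeb2. Named genes also followed a rule fixed in advance. First came a set named in any case: Ep300, Rxra, Sp5, Zeb2, Pou5f1, Nanog, Esrrb, Klf4, T, Cdx2, Tbx6, Meox1, Axin2, Cdh1, Cyp26a1, Rarb and Dhrs3. Second came the genes of the 5 regions of each class with the highest −log10 q in the weaker replicate, and last up to 4 members of each list with the most regions of the classes compared.

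The alternatives chosen before the data were examined were keeping the peaks at input peaks, using only peaks with a −log10 q of 5 or more, requiring summits within 250 bp, using lists of equal length (each reduced to its strongest peaks), leaving out each replicate in turn, pairing replicates by number, a gene-end window of 2.5 kb, assignment within 20 kb, Fisher's exact test over regions for the lists, and distal regions only. When a replicate was left out, every peak of the library that remained in that group counted as a region. Counts in that setting are therefore not of regions found in both replicates of the group. Assignment of regions inside a gene to that gene, distal regions alone for the pairs of factors, and random draws of Hox genes as runs of neighbours were added after the data had been seen. No genome sequence was used here, so the 5 planned searches for sequence motifs were not made.

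The tests were tested on simulated data. A list of 20 genes moved by 25 points was called in 90% of 100 simulations for the p300 comparison, 85% for RXRα between cell types, and 100%, 99% and 97% for RXRα, Sp5 and Zeb2 at p300 regions. Unchanged lists were called in 0.125%, 0.0625%, 0.3125%, 0.1875% and 0.1875% of cases, in the same order. The placement test called unrelated regions in 2% of simulations, the odds ratio intervals covered the simulated value in 98%, and 100% of 4573 simulated pileups were recovered. Unrelated regions were placed by the same rule as the test's own placements, so that rate was set in advance. The list and odds ratio simulations drew each region independently, with the same probability for all unchanged genes. These rates therefore do not show how the tests behave on clustered regions. Only a move of 25 points was simulated. The differences from random lists at p300 regions were smaller, such as 6.63 points for Sp5 at Wnt targets and 17.2 for Zeb2 at Hox genes. How often differences of that size are missed was not simulated. Overlaps and nearest gene ends were checked against exhaustive searches and did not differ. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used, with random draws seeded.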

Results

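The series comprised 12 immunoprecipitation libraries and 2 inputs, in 8 groups. p300, a coactivator that marks active enhancers, and RXRα, a nuclear receptor that pairs with the retinoic acid receptors, were each profiled in mESCs and in 120 h gastruloids. Sp5, a zinc-finger factor induced by Wnt signalling, and Zeb2, a repressor of epithelial genes, were profiled in gastruloids only. After removal of peaks at input peaks, the p300 lists held 44506 and 35371 peaks in mESCs and 63117 and 75346 in gastruloids. RXRα had 49661 and 28112 peaks in mESCs and 29867 and 3111 in gastruloids, Sp5 had 19714 and 11932, and Zeb2 had 44310 and 12222. The inputs gave 111 peaks in mESCs and 514 in gastruloids. Recovered fragment densities ran from 5.50 to 11.4 per kb in the immunoprecipitations and were higher in mESCs than in gastruloids.

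Of the peaks in the first p300 gastruloid replicate, 84.1% were also in the second, and 72.3% the other way round. RXRα in gastruloids was far less even: 76.0% of the peaks of the short second list were in the first, but only 7.89% of the first were in the second. Zeb2 had 88.1% and 23%, Sp5 92.1% and 56.6%, RXRα in mESCs 88.5% and 50.0%, and p300 in mESCs 88.1% and 69.8%. Regions found in both replicates numbered 31014 for p300 in mESCs, 53025 for p300 in gastruloids, 24698 for RXRα in mESCs, 2352 for RXRα in gastruloids, 10953 for Sp5 and 10172 for Zeb2. The labels do not say whether replicates came from separate cultures. All p-values therefore measure spread among these regions or genes, which are not replicates, and say nothing of variation between cultures.

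**Figure D1:**
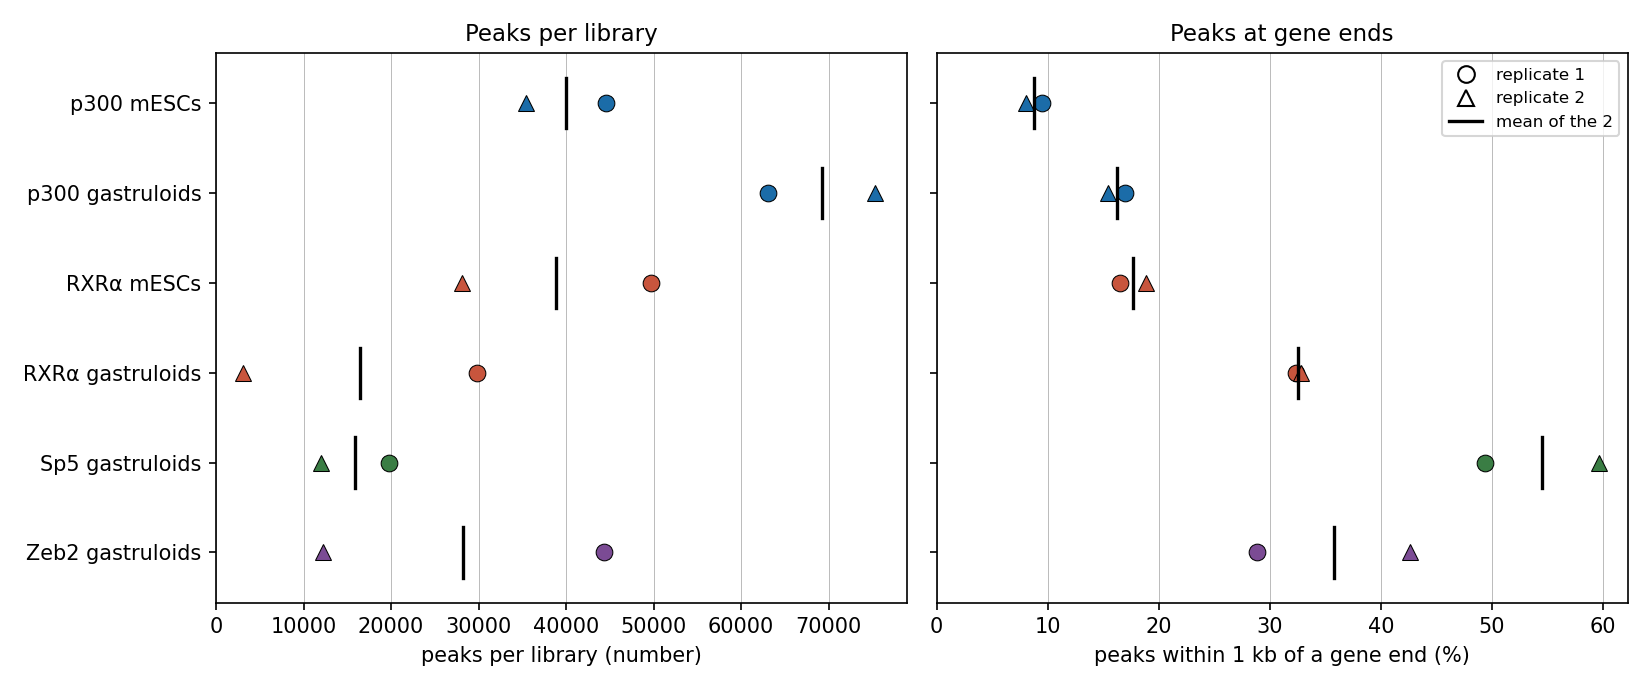
Peaks per library (left, number of peaks) and share of peaks within 1 kb of a gene end (right, percent) for the 6 immunoprecipitation groups, with replicate 1 as circles, replicate 2 as triangles and the mean of both as bars. The RXRα gastruloid lists held 29867 and 3111 peaks, and the gene-end share ran from 8.02% in a p300 mESC library to 59.6% in an Sp5 library.

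The p300 lists of mESCs and gastruloids differed widely. Around Cyp26a1, which encodes the enzyme that degrades retinoic acid, 8 gastruloid-only regions and no mESC-only region were found. Axin2, a feedback target of Wnt signalling, had 9 and 0, Dhrs3, which encodes a retinal reductase, 9 and 0, and the tail bud gene T 3 and 0. The pluripotency gene Esrrb had 6 gastruloid-only and 8 mESC-only regions, and Nanog kept 2 shared regions with none of either class. In all, 34812 regions were gastruloid-only, 65.7% of the gastruloid regions, 13793 were mESC-only, 44.5% of the mESC regions, and 13599 were shared. The excess of gastruloid-only regions came with longer gastruloid lists: with lists of equal length there were 17961 gastruloid-only, 17563 mESC-only and 9037 shared regions, and Esrrb had 2 and 10. Without the first gastruloid replicate 53609 regions were gastruloid-only, and without the second mESC replicate 22393 were mESC-only.

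The strongest gastruloid-only p300 regions included 1 inside the Hoxa cluster, 751 bp from an end of Hoxa4, with folds of 19.5 and 21.7, and 1 lying 2042 bp from F11r, which encodes a tight-junction protein (25.8 and 28). Another lay 54185 bp from Htatip2 (26.5 and 28.7), and the other 2 of the top 5 lay more than 100 kb from any gene end. In mESCs the strongest lay more than 100 kb from any gene end (folds of 28.8 in both replicates), and the other 4 of the top 5 were near Epha4, an ephrin receptor gene (18.1 and 16.8), Spred2 (20.4 and 19.4), Serp2 (19.6 and 19.9) and Zfp825 (24.7 and 23.8). Around the genes of the profiled proteins, p300 regions were gained in gastruloids: 6 gastruloid-only and 0 mESC-only at Rxra, 5 and 0 at Sp5, 11 and 2 at Zeb2, and 3 and 0 at Ep300 itself. With lists of equal length Zeb2 had 7 and 2. The strongest at Cyp26a1 lay 29680 bp from the gene, with a fold of 25.9 ± 2.46 (n = 2), and the strongest at Dhrs3 lay inside the gene at 23.7 ± 2.84 (n = 2).

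The shift was largest in the lists of Hox, somite and streak genes. All 31 Hox genes with regions of either class, which set position along the body axis, had more gastruloid-only than mESC-only regions, among them Hoxc4 (9 of 10 gastruloid-only), Hoxb1 (6 of 7) and Hoxb4 (5 of 5). Of 19 genes of the presomitic mesoderm and somites, the tissue that forms the vertebral segments, 18 had more and 1 had equal numbers, with Pax3 at 16 of 17, Uncx at 10 of 10, Meox1 at 5 of 5 and Tbx6 at 2 of 2. Primitive streak and tail bud genes divided the same way, 18 with more and 1 equal, with Lhx1 at 8 of 8, Eomes at 5 of 7, T at 3 of 3 and Cdx2 at 3 of 3. Pluripotency genes were split: 9 of 20 had more gastruloid-only regions, 8 had fewer and 3 had equal numbers, with Sox2 at 6 of 11, Nr5a2 at 9 of 14, Klf4 at 3 of 5 and Pou5f1 at 0 of 1.

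Across all genes 71.1% of the assigned regions of a single cell type were gastruloid-only (27202 of 38239). The share was 96.4% for the Hox list (80 of 83; median of random lists 70.9%; adjusted permutation p = 0.0016), 91.8% for presomitic mesoderm and somites (78 of 85; 70.9%; adjusted p = 0.0016), and 86.3% for streak and tail bud (63 of 73; 70.2%; adjusted p = 0.0136). It was 50.0% for pluripotency (49 of 98; 70.8%; adjusted permutation p = 0.00213). The unadjusted permutation p of the Hox and somite lists, 0.0002, is the smallest that the two-sided draws of random lists can give. The streak list ended above the threshold without the first gastruloid replicate (adjusted permutation p = 0.0568). Drawing Hox genes as runs of neighbours left the Hox list at an adjusted permutation p of 0.0016.

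The other 12 lists stayed above the adjusted threshold. The trophoblast list came nearest, at 50.0% (21 of 42; p = 0.0218, adjusted permutation p = 0.0698), with Tfap2c, a trophoblast and germ cell regulator, at 3 of 12 and Tead4 at 1 of 5. It passed by Fisher's exact test (adjusted p = 0.0176), without the second gastruloid replicate (0.0339) and without the first mESC replicate (0.0384). Retinoic acid signalling stood at 79.0% (98 of 124, adjusted permutation p = 0.206), with Meis2 at 15 of 19, Meis1 at 15 of 18 and Rarb at 2 of 2. Neural tube stood at 77.5% (Irx3 11 of 12, Sox1 5 of 11), Wnt targets at 75.8% (Tcf7l1 10 of 16) and lipid nuclear receptor targets at 63.6% (Abca1 8 of 13), all with an adjusted permutation p of 0.490, as for BMP and TGF-beta feedback at 63.6% (Id4 5 of 11). Endoderm and notochord (74.6%, Foxa2 6 of 8), neural crest (73.6%, Sox9 10 of 12), cardiac and lateral plate mesoderm (72.2%, Tbx5 6 of 7) and endothelium and blood (69.0%, Runx1 11 of 16) each had 0.828. Epithelial identity and EMT stood at 70.9% (Tjp1 11 of 11, Cdh1 2 of 6, Zeb2 11 of 13, adjusted permutation p = 0.946). This share joins epithelial and mesenchymal genes, which were not tested apart. The adult tissue control stood at 83.3% (15 of 18, adjusted permutation p = 0.538).

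**Figure D2:**
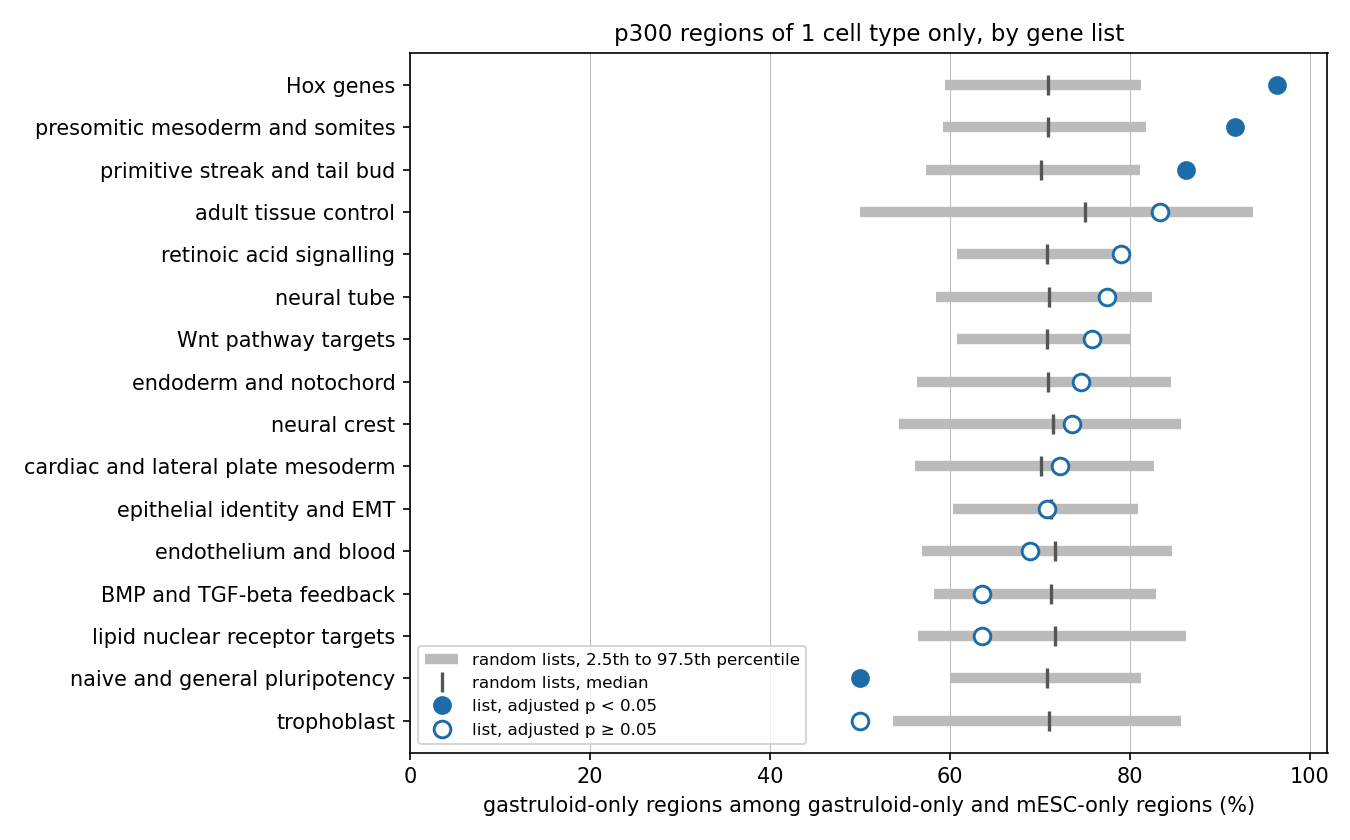
Share of gastruloid-only regions (percent) among the p300 regions of a single cell type, for each of the 16 gene lists; points are the lists, filled where the adjusted permutation p was under 0.05, and grey bars span the central 95% of 10000 random lists, with the median as a tick. Hox (96.4%), somite (91.8%) and streak (86.3%) lists lay above the random range and pluripotency (50.0%) below it. Trophoblast (50.0%) also lay below its range, but its adjusted permutation p was 0.0698.

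Gastruloid-only p300 regions lay at gene ends more often than mESC-only ones, although most regions of both classes were distal. Within 1 kb of a gene end were 6289 of 34812 gastruloid-only regions (18.1%), 538 of 13793 mESC-only regions (3.90%) and 11.5% of shared regions. Of the gastruloid-only regions 39.5% were inside genes and 42.4% between them, against 44.9% and 51.2% of the mESC-only regions. Taken library by library, peaks absent from the other cell type were at gene ends in 16.1 ± 1.18% (n = 2) in gastruloids and 4.39 ± 0.303% (n = 2) in mESCs. The difference was 14.2 points, with an odds ratio of 5.43 (95% interval 4.96 to 5.95); the p of Fisher's exact test, two-sided, was too small to be represented.

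Most RXRα regions of a single cell type were found in mESCs only: 1 of 99 near pluripotency genes was gastruloid-only (1.01%), against 2.58% of all assigned regions. In the main setting the pluripotency list was not past the threshold (median of random lists 2.06%, adjusted permutation p = 0.678). A low share could not have been called there, as the 2.5th percentile of these random lists was 0%. These shares rest on the short second gastruloid list. Without it, with each peak of the first gastruloid library counted as a region, the pluripotency list lay 22.8 points below random lists. All 22 pluripotency genes with regions of a single cell type had fewer gastruloid-only than mESC-only RXRα regions. With so few gastruloid-only regions this was not particular to the list: all 17 such Wnt target genes and all 14 lipid nuclear receptor target genes had fewer too. Esrrb and Klf4 each had 8 mESC-only regions and 0 gastruloid-only, Nanog and Pou5f1 each 4 and 0, Tbx3 11 and 0, and Tfcp2l1 9 and 0. The strongest at Esrrb lay inside the gene, with a fold of 16.9 ± 0.861 (n = 2), and the strongest at Nanog lay 4554 bp away. Cyp26a1 had 1 gastruloid-only region, 38506 bp from the gene, 0 mESC-only and 2 shared regions. Dhrs3 had 1 gastruloid-only region inside the gene, with folds of 19.2 and 9.63, beside 2 mESC-only and 2 shared regions. Of the 5 strongest gastruloid-only regions 4 lay near Ccdc85a (40.8 and 20.8), Myl12b (22.3 and 24.1), Metrn (30.9 and 13.4) and Tmem132e (15.4 and 10.4) and 1 more than 100 kb from any gene end, and the strongest mESC-only ones near Specc1, Wrap53, Sgsm1, Cct8l1 and Actr2.

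In all, 475 RXRα regions were gastruloid-only, 15973 mESC-only and 1588 shared; the shared ones made up 67.5% of the gastruloid regions and 6.43% of the mESC regions. These counts depended on the short second gastruloid list, and without it 15672 regions were gastruloid-only, 16021 mESC-only and 8719 shared. Each peak of the first gastruloid library then counted as a region, which by construction raises the gastruloid-only and shared counts. The same holds for mESC-only counts when an mESC replicate is left out. Without the second mESC replicate 36563 were mESC-only, with lists of equal length there were 908, 2032 and 370, and with a −log10 q of at least 5 there were 274 gastruloid-only and 872 shared regions. At gene ends were 81 of the 475 gastruloid-only regions (17.1%) and 1060 of the 15973 mESC-only ones (6.64%), a difference of 10.4 points (odds ratio 2.89, 95% interval 2.26 to 3.70; Fisher's exact test, two-sided, p = 2.83e-14). Without the first gastruloid replicate the difference turned to −2.12 points (Fisher's exact test, two-sided, p = 0.0574), and without the second it was 16.3 points. It was 17.2 points without the first mESC replicate, 27.4 with lists of equal length and 3.72 with a −log10 q of at least 5. For single libraries the shares were 23% and 14.0% in gastruloids, a mean of 18.5 ± 6.35% (n = 2), and 7.85 ± 0.269% (n = 2) in mESCs. Shared regions stood at 45.3%.

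The share of gastruloid-only RXRα regions was above that of random lists in 4 lists, which held few of these regions. In all, 376 of 14553 assigned regions of a single cell type were gastruloid-only (2.58%). Among Hox genes they were 7 of 14 (50.0%; adjusted permutation p = 0.00107), with Hoxb1 at 1 of 3 and Hoxb3 and Hoxc4 each at 1 of 2. In retinoic acid signalling they were 8 of 41 (19.5%; median of random lists 2.5%; adjusted permutation p = 0.00107), 4 of them among the 7 of Meis1, a Hox cofactor gene, and none among the 5 of Cyp26b1. In the neural tube list they were 6 of 18 (33.3%; adjusted permutation p = 0.00107), with Pax7 at 2 of 5, Irx3 at 2 of 2 and Sox1 at 1 of 3, and in endoderm and notochord 4 of 16 (25.0%; adjusted p = 0.0056), with Foxa2 at 1 of 2 and Prdm1 at 0 of 4. Of these only the Hox list kept its call throughout, including with Hox genes drawn as runs of neighbours (adjusted permutation p = 0.00107). The retinoic acid list lost it without the second gastruloid replicate (0.0595) and with assignment within 20 kb (0.0528), and the neural tube list with lists of equal length (0.0540) and within 20 kb (0.128). The endoderm list lost it in 5 settings, among them the omission of either gastruloid replicate (0.154 and 0.241).

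The other 12 RXRα lists were not past the threshold: cardiac and lateral plate mesoderm 2 of 17 (adjusted permutation p = 0.365), streak and tail bud 2 of 22 (0.633), Wnt targets 2 of 50, endothelium and blood 1 of 18 and pluripotency 1 of 99 (0.678 each), presomitic mesoderm and somites 1 of 20, epithelial identity 1 of 41 and BMP and TGF-beta feedback 1 of 33 (1 each). No gastruloid-only region was found among the 13 of neural crest, 25 of lipid nuclear receptor targets, 23 of trophoblast and 3 of the adult control (1 each). The 2.5th percentile of random lists was 0% for every list, so this comparison could not call a low share.

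In gastruloids most RXRα, Sp5 and Zeb2 regions coincided with p300. At Cyp26a1, 4 of the 8 p300 regions held RXRα, 2 held Zeb2 and 1 held Sp5, and at Dhrs3 2, 1 and 2 of 10 did. Of the 5 strongest RXRα regions of gastruloids 4 lay near Rab10, Ski, Dusp5 and Camk1d, and 1 lay more than 100 kb from any gene end. p300 was present at 2017 of 2352 RXRα regions (85.8%), 9282 of 10953 Sp5 regions (84.7%) and 7964 of 10172 Zeb2 regions (78.3%). Placements at random gave means of 2.55%, 2.62% and 2.94% and at most 3.70%. Each one-sided p was 0.000999, the smallest that 1000 random placements can give. Such placements are not kept to places where libraries tend to give peaks, so this p does not show specific coincidence with p300. Of the 514 peaks of the gastruloid input, made without antibody, 460 (89.5%) and 463 (90.1%) were also in the p300 gastruloid lists before removal. In single libraries 63.8 ± 7.11% (n = 2) of RXRα, 75.8 ± 9.12% (n = 2) of Sp5 and 60.3 ± 12.6% (n = 2) of Zeb2 peaks were at p300 regions. In mESCs 10902 of 24698 RXRα regions (44.1%; random 1.46%; one-sided permutation p = 0.000999) were at mESC p300 regions. With the lists of each factor and of p300 in gastruloids cut to the shortest among them, the gastruloid shares were 20.5%, 13% and 23.1%. That length was 3111 peaks for RXRα, 11932 for Sp5 and 12222 for Zeb2, so these shares are not comparable between factors.

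**Figure D3:**
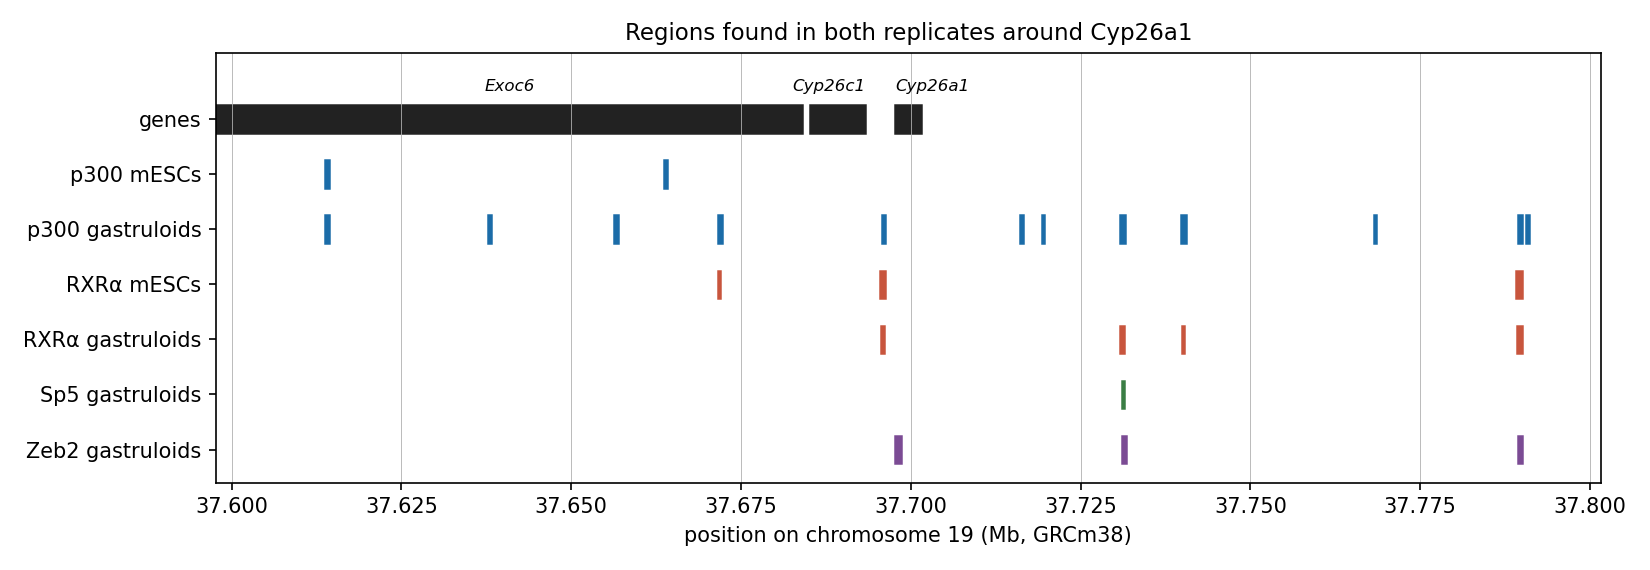
Regions found in both replicates of each group (boxes, 1 line per group) and protein-coding genes (black) around Cyp26a1 on chromosome 19, by position in Mb. The p300 regions to the right of the gene appear in gastruloids only, and 1 of them, 29680 bp away, carries RXRα, Sp5 and Zeb2.

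Seen from p300, 2014 of the 53025 gastruloid regions held RXRα (3.8%), 9191 held Sp5 (17.3%) and 7950 held Zeb2 (15.0%), while 39472 held none. The RXRα count rests on the short second list: peaks of the first RXRα replicate alone were at 16163 of the 53025 regions (30.5%). The Zeb2 count and the count with none depend on list length too, as the second Zeb2 list held 12222 peaks against 44310 in the first. The factors, all taken here from gastruloids, were nearly absent from p300 regions found in mESCs only. This follows largely from the classes: mESC-only regions overlap no gastruloid p300 peak, and 78.3% to 85.8% of factor regions lay at gastruloid p300 regions. No share to be met without such overlap was computed. Sp5 was found at 15.8% of gastruloid-only, 13.8% of shared and 0.225% of mESC-only p300 regions. The shares were 13.5%, 14.3% and 0.515% for Zeb2 and 3.12%, 4.28% and 0.160% for RXRα. Zeb2 and Sp5 shared 4238 p300 regions, with an odds ratio of 9.25 (95% interval 8.77 to 9.75); the pair Sp5 and RXRα shared 1044 (5.66, 5.17 to 6.20) and the pair Zeb2 and RXRα 963 (5.77, 5.27 to 6.32). Adjusted p from Fisher's exact test, two-sided, was 5.81e-286 and 1.19e-279 for the last pairs and too small to be represented for the first. Sp5 regions were at gene ends most often, in 62.4%, against 45.4% for Zeb2, 38.9% for RXRα and 18.1% for p300. The order of Zeb2 and RXRα depended on the library, with 28.8% and 42.6% of peaks for Zeb2 and 32.3% and 32.8% for RXRα. The odds ratio of Sp5 and Zeb2 was 4.22 within strata of p300 fold and position, and its binary logarithm, 3.21, rose to 5.11 without the second Zeb2 replicate and fell to 2.51 with summits within 250 bp. For Sp5 with RXRα this logarithm ran from 1.92 to 3.87 and for Zeb2 with RXRα from 1.76 to 3.33. The HA-tagged factors were precipitated with the same HA antibodies, and no HA precipitation from untagged cells was analysed here.

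**Figure D4:**
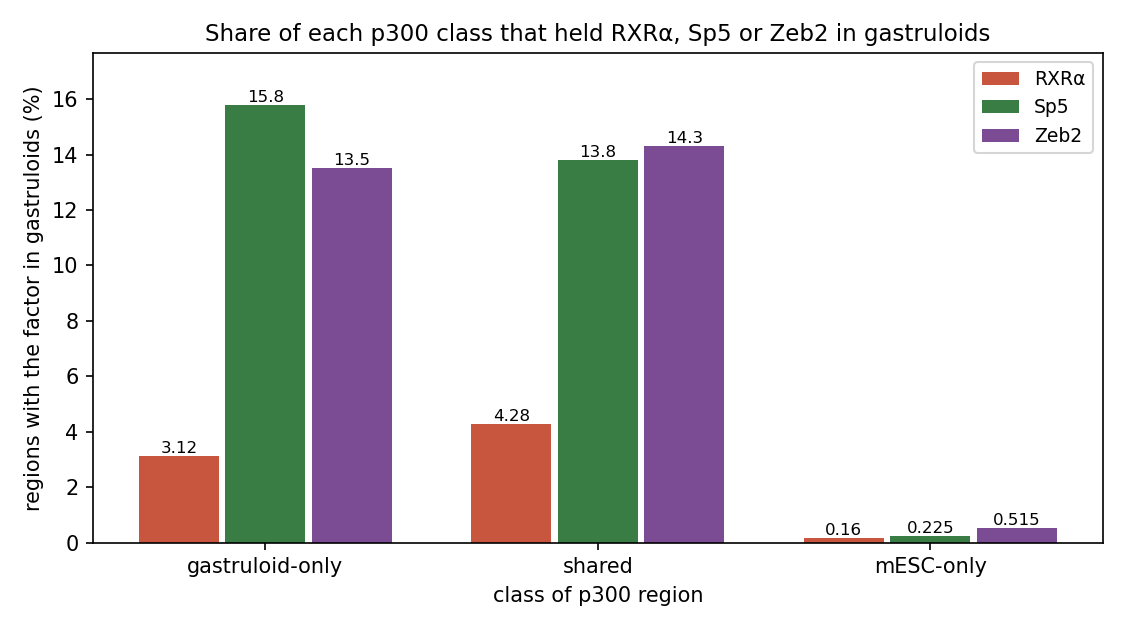
Share of gastruloid-only, shared and mESC-only p300 regions (percent, bars) that overlapped an RXRα, Sp5 or Zeb2 region of gastruloids. Sp5 reached 15.8% of gastruloid-only and 0.225% of mESC-only regions. The low mESC-only shares follow largely from the class definition, as these regions overlap no gastruloid p300 peak.

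RXRα was found with p300 at retinoid and lipid-sensor genes. Besides Cyp26a1, it was found at 4 of 17 p300 regions of Meis1, 4 of 17 of Meis2, and 2 of 4 of Crabp2, which encodes a retinoic acid carrier. In the Hox clusters it was at 2 of 4 regions of Hoxa3 and 2 of 9 of Hoxc4, and among lipid nuclear receptor targets at 2 of 8 of Abca1 and 1 of 7 of Abcg1, which encode cholesterol transporters. Rarb and Rxra had none, of 4 and 9 regions. Over all assigned p300 regions the share with RXRα was 4.28% (1819 of 42519). It was 17.4% for the Hox list (16 of 92; adjusted permutation p = 0.0016), 16.3% for retinoic acid signalling (22 of 135; adjusted p = 0.0016) and 15.8% for lipid nuclear receptor targets (9 of 57; adjusted p = 0.00533), against medians of 4.17%, 3.85% and 3.57% in random lists. These calls did not hold under every setting. Without the second RXRα gastruloid replicate the retinoic acid and lipid lists had an adjusted permutation p of 0.0736, and with lists of equal length the Hox and lipid lists had 0.726 and 0.390; drawing Hox genes as runs gave 0.00533.

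At p300 regions the neural tube list of RXRα (7 of 87, 8.05%, adjusted permutation p = 0.316) passed without the second replicate (0.0048) and with distal regions only (0.0440). The remaining lists were BMP and TGF-beta feedback (8.11%, 0.324), endoderm and notochord (7.69%, 0.456), streak and tail bud (6.90%, 0.456), pluripotency (5.93%, 0.463), endothelium and blood (0 of 54, 0.463), epithelial identity (4.07%, 1), cardiac and lateral plate mesoderm (3.92%, 0.991), neural crest (3.51%, 1), somites (3.13%, 0.955), Wnt targets (2.88%, 0.936), trophoblast (2.78%, 0.979) and the adult control (0 of 21, 0.961).

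No gene list passed the adjusted threshold for Sp5 at p300 regions. Among single genes, Sp5 held 4 of 7 p300 regions of Nkd1, an inhibitor of Wnt signalling, 4 of 16 of Tcf7l1 and 3 of 11 of Lef1. It held 3 of 5 of Wnt5b, 3 of 3 of the segmentation clock gene Hes7, and 2 of 6 of its own gene, the strongest lying 17783 bp away with a fold of 16.1 ± 0.962 (n = 2). The strongest Sp5 regions of all lay near Zfp503, Prdm9, Ehbp1, Lamtor3 and Zfp408. The share of p300 regions with Sp5 was 20.9% among all assigned regions, and 0 of 16 lists passed after adjustment in the two-sided test against random lists, while 4 had an unadjusted permutation p under 0.05. Wnt targets were above random lists (27 of 139, 19.4% against 12.8%; permutation p = 0.0256), and cardiac and lateral plate mesoderm (2 of 51, 3.92%; p = 0.0032), endoderm and notochord (4 of 65, 6.15%; p = 0.0132) and pluripotency (10 of 118, 8.47%; p = 0.0350) below. Their adjusted p-values were 0.137, 0.0512, 0.106 and 0.140, and up to 4 lists passed under other settings.

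The other lists of Sp5 were lipid nuclear receptor targets (28.1%, adjusted permutation p = 0.293), Hox genes (22.8%, 0.610), streak and tail bud (19.5%, 0.525), neural tube (19.5%, 0.525), BMP and TGF-beta feedback (18.9%, 0.526), trophoblast (16.7%, 0.876), somites (14.6%, 0.823), adult control (14.3%, 0.486), retinoic acid signalling (14.1%, 0.946), epithelial identity (11.4%, 0.303), neural crest (10.5%, 0.525) and endothelium and blood (9.26%, 0.303).

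Zeb2 passed the adjusted threshold in the Hox and epithelial lists, with calls that depended on the setting. It held 3 of 4 p300 regions of Dsp, which encodes desmoplakin, 3 of 12 of Grhl2, an activator of epithelial genes, 3 of 16 of Tjp1 and 2 of 9 of Epcam. A Zeb2 region with a fold of 10.7 ± 0.7 (n = 2) lay 14 bp from an end of Cdh1, which encodes E-cadherin, although none of the 4 p300 regions of Cdh1 held Zeb2. Zeb2 also held 5 of 5 regions of Hoxb4 and 2 of 14 of its own gene. Of its 5 strongest regions 2 lay near Cacng4 and 1 each near Pisd, Celsr1 and Fcgr1. The share was 17.1% among all assigned regions, 33.7% for the Hox list (31 of 92; random 16.5%; adjusted permutation p = 0.0064) and 26.0% for epithelial identity (32 of 123; random 15.3%; adjusted p = 0.0256). Neither call held under every setting. The Hox list rose above the threshold with Hox genes drawn as runs of neighbours (0.0592), with lists of equal length (0.0896) and within 20 kb (0.0864). The epithelial list did so with summits within 250 bp (0.180), equal lengths (1), without the first or second Zeb2 replicate (0.136 and 0.177), within 20 kb (0.174), by Fisher's exact test (0.0938) and with distal regions only (0.0659).

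The Zeb2 lists nearest the threshold were Wnt targets (30 of 139, 21.6%, adjusted permutation p = 0.0768; 0.0096 without the second Zeb2 replicate and 0.0160 without the second p300 gastruloid replicate), with 6 of 15 at Znrf3, and endoderm and notochord (17 of 65, 26.2%, 0.109). The rest were streak and tail bud (20.7%, 0.334; 0.0171 without the second Zeb2 replicate), BMP and TGF-beta feedback (20.3%, 0.397), the adult control (4.76%, 0.295), somites (11.5%, 0.714), and, at 0.856, pluripotency (12.7%), neural tube (12.6%), endothelium and blood (11.1%), retinoic acid signalling (15.6%) and lipid nuclear receptor targets (14.0%). Neural crest (15.8%), cardiac and lateral plate mesoderm (13.7%) and trophoblast (16.7%) had 0.916.

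**Figure D5:**
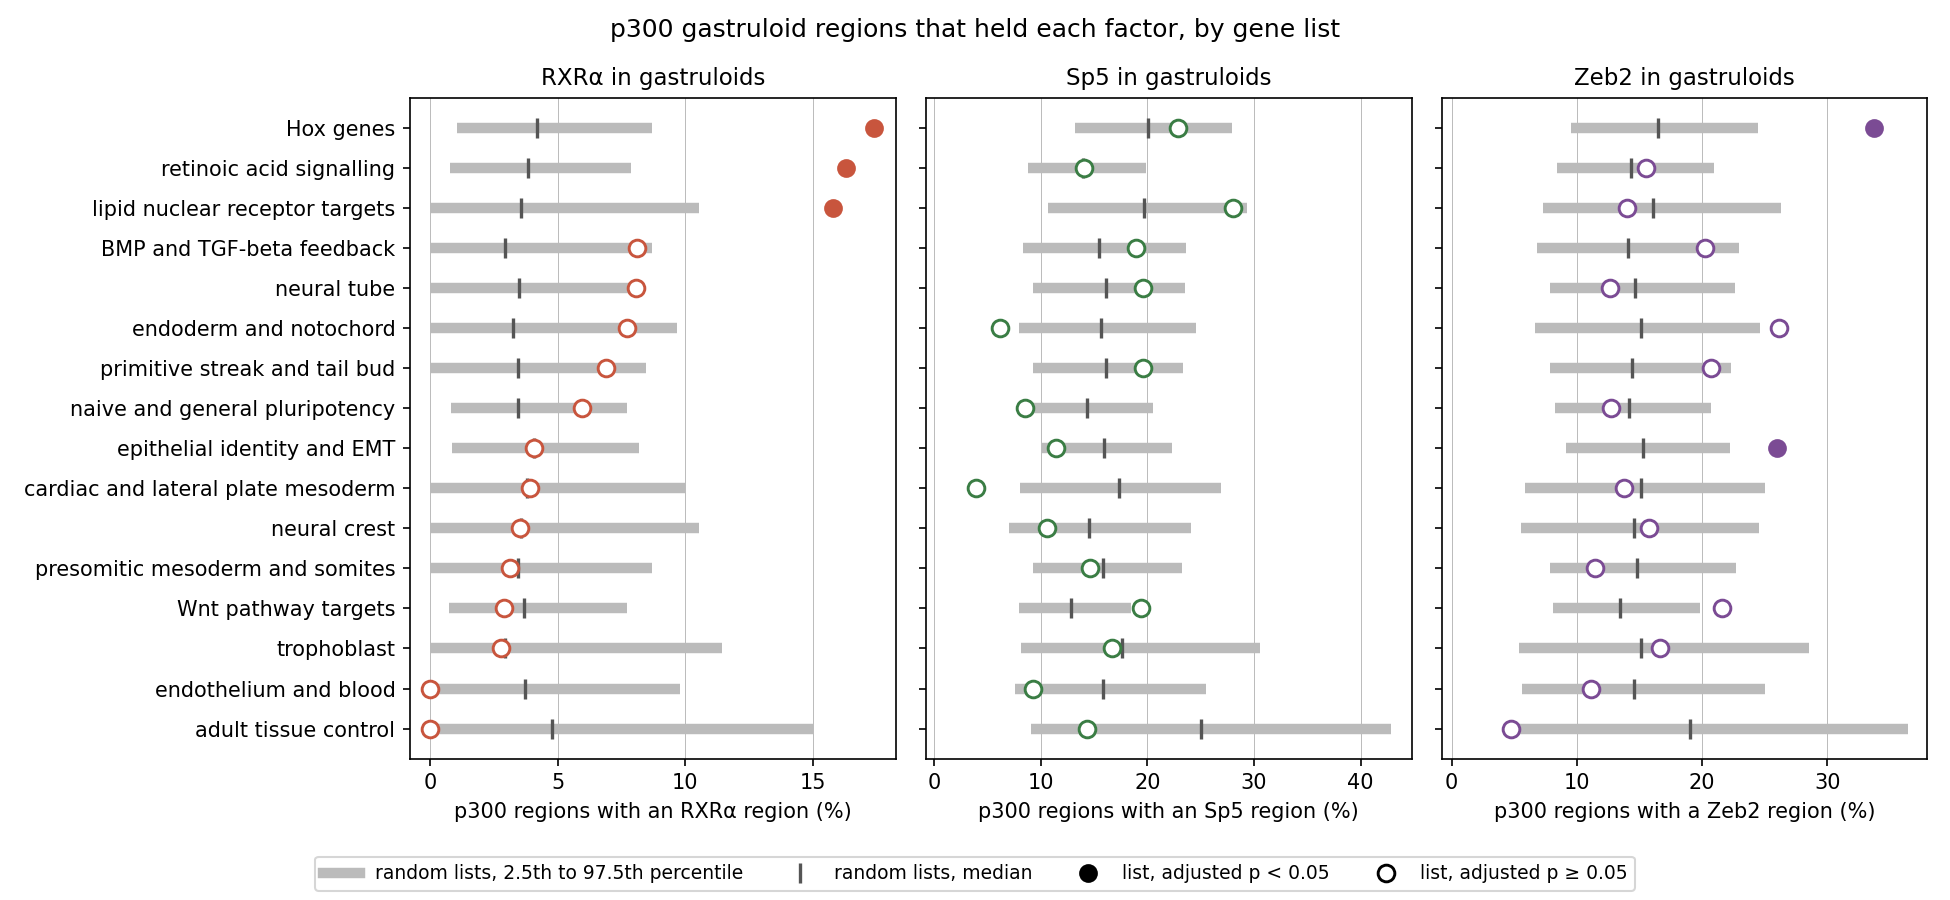
Share of p300 gastruloid regions (percent) that overlapped RXRα, Sp5 or Zeb2 for each of the 16 gene lists; filled points had an adjusted permutation p under 0.05 against 10000 random lists, whose central 95% are grey bars with the median as a tick. RXRα stood out at Hox (17.4%), retinoic acid (16.3%) and lipid nuclear receptor (15.8%) genes, and Zeb2 at Hox (33.7%) and epithelial and EMT (26.0%) genes.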

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

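The comparison of odds ratios, the gene-end share of the input peaks, and the tests on fragment density and on the length of the RXRα lists were chosen only after results had been seen; the other tests here were written before the data were examined or before their own result was seen.

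A pair of results called for a closer look. The odds of lying at a gene end rose from mESC-only to gastruloid-only regions for both p300 and RXRα, and in the main setting more for p300: odds ratios of 5.43 and 2.89, a ratio of 1.88 between them (normal approximation on the log scale, z = 4.70). That z takes the p300 and RXRα regions as independent, although 350 of the 475 gastruloid-only RXRα regions lay at gastruloid-only p300 regions. The RXRα side of this difference rests on those 475 regions and changed with the setting. Odds ratios were computed in the main setting only. In points, the RXRα difference was −2.12 points without the first RXRα gastruloid replicate, 16.3 without the second and 17.2 without the first mESC replicate, against 14.2 for p300, and with lists of equal length it was 27.4 points against 12.2. The gastruloid input, used only to remove peaks, had 346 of its 514 peaks at gene ends (67.3%; 3.44% for the same peaks placed at random, one-sided permutation p = 0.000999). The mESC input had 30.6% of 111 peaks there.

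The rise of p300 at gene ends in gastruloids was weighed first. Longer gastruloid lists are not the cause, since with lists of equal length the difference was 12.2 points against 14.2. Signal that any gastruloid library gives at gene ends is a candidate explanation: regions of the other factors covered 71.8% of gastruloid-only p300 regions at gene ends against 13.4% of distal ones, a ratio of 5.36, which true joint binding would also give. The input does not decide whether chromatin without antibody adds to the rise: its gene-end share of 67.3% was above the 16.2 ± 1.09% (n = 2) of the p300 gastruloid libraries, but the mESC input stood above its p300 libraries too (30.6% against 8.77 ± 1.06%, n = 2). Peaks at input peaks had been removed, and keeping them gave a difference of 14.7 points. New binding at promoters in differentiating cells remains possible, and a control precipitation from untagged gastruloids would separate these readings.

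The short RXRα list of the second gastruloid replicate, 3111 peaks against 29867, was weighed next. Lower depth is not the cause, since the fragment density of the first replicate was only 1.06 times that of the second. Weaker enrichment is consistent with the values: at regions in both lists the fold was lower in the second replicate in 93.9% of cases (medians 11.9 and 5.43), although Sp5 reached 92.6% with a far smaller gap in list length. Nor is depth the whole cause of the few RXRα regions in both gastruloid replicates: the first gastruloid list, at a lower density than either mESC library, was 1.06 times as long as the shorter mESC list (29867 against 28112). Whether depth shortened the first list against the longer mESC list of 49661 peaks cannot be told apart from a biological loss, as the density of the mESC libraries was 1.39 times higher on average. The counts of RXRα regions by class should be read with that in mind.

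The joint presence of Sp5 and Zeb2 at p300 regions was weighed last. Strength and position of the p300 region are not the whole cause, as the odds ratio within strata of both was 4.22, although it fell from 9.25 without strata, so a part goes with them. Gene ends that take every factor are not the whole cause either, as the odds ratio was 9.50 among distal regions. Most joint regions were at gene ends all the same: 70.15% of those held by both, against 6.24% of those held by neither. The 4.22 is pooled over gene-end and distal strata and lies below the 9.50 of distal regions, so it need not hold at either position. No odds ratio at gene ends alone was computed, so the distal value does not say how much gene ends add. Signal of the shared HA antibodies at fixed places could produce it: peaks of the first RXRα gastruloid replicate covered 86.9% of the p300 regions held by both, 72.1% of those held by Sp5 alone, 50.2% by Zeb2 alone and 17.6% by neither. RXRα regions found in both replicates were at only 643 of the 4238 regions held by both. The second RXRα list, made with the same antibodies at a similar fragment density, held 3111 peaks in all. Whether its weaker enrichment hid signal at fixed places was not tested. High coverage by the first list would also be seen if all 3 proteins met at the most open regions. The lists cannot rank the antibody reading against true joint binding.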

How the results depend on the processing

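With 2 replicates per group, peak lists without reads, gene ends in place of promoters and regions assigned by nearness alone, both counts and shares depend on list length. With lists of equal length 20.5%, 13% and 23.1% of RXRα, Sp5 and Zeb2 regions were at p300, and there were 17961 gastruloid-only and 9037 shared p300 regions, 908 gastruloid-only, 2032 mESC-only and 370 shared RXRα regions, and 2, 1 and 0 lists passed for RXRα between cell types, RXRα at p300 and Zeb2 at p300. The cause was not tested beyond the loss of weak peaks that this setting makes by construction. With a −log10 q of at least 5, 274 RXRα regions were gastruloid-only and 872 shared, and 2 Sp5 lists passed. Keeping peaks at input peaks gave 1 Sp5 list. With genes within 20 kb, 1 list passed for RXRα between cell types, 3 for Sp5 and 0 for Zeb2. Fisher's exact test over regions gave 4 lists for Sp5 and 1 for Zeb2. Summits within 250 bp gave 1 Zeb2 list, distal regions 1, and assignment by gene span, added after the data had been seen, 1 Sp5 list.

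Leaving out each replicate in turn gave 35856 to 53609 gastruloid-only and 15085 to 22393 mESC-only p300 regions. In the group that lost a replicate, each peak of the remaining library counted as a region, so counts of that group rise by construction. For RXRα the ranges were 513 to 15672 gastruloid-only, 16021 to 36563 mESC-only and 1614 to 8719 shared, and −2.12 to 17.2 points for the gene-end difference, the only result that turned. Lists passing ran from 0 to 1 for Sp5 and from 1 to 3 for Zeb2. The widest changes in RXRα gastruloid-only and shared counts came with the omission of the gastruloid list of 3111 peaks.

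With the replicate number as a replicate block, 34928 p300 regions were gastruloid-only, 13849 mESC-only and 13393 shared, and 482, 16026 and 1544 for RXRα. The gene-end differences were 14.3 and 11.1 points, and 4 lists passed for each protein. The numbers do not show that replicates were paired: 42.4% and 48.4% of p300 mESC peaks were in the gastruloid list of the same number, and 45% and 45.6% in the other.

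Of the main results 169 stayed, 29 moved and 1 turned over all alternatives. A count stayed when it lay within a factor of 1.5 of its main value. A test stayed when its direction and its side of the threshold held, whatever its size. The RXRα gene-end difference of 27.4 points with lists of equal length, against 10.4, thus counted as having stayed. Of results on single lists and pairs 951 stayed, 24 fell short of the threshold and 21 newly passed it, and of counts at named genes 11492 stayed and 1884 moved. With Hox genes drawn as runs of neighbours, also added afterwards, the Hox list at p300 kept its call for p300 and RXRα and lost it for Zeb2 (adjusted permutation p = 0.0592). The alternatives for motifs were not run, since no genome sequence was used here.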

Other observations

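The comparison of p300 and RXRα classes and of Zeb2 with Sp5 was written before its result was seen; the joint regions of all 3 factors and the genes with the most p300 regions were chosen only after results had been seen.

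Gastruloid-only RXRα regions lay mostly at gastruloid-only p300 regions, while most mESC-only RXRα regions did not lie at changed p300 regions. Of the 475 gastruloid-only RXRα regions, 350 lay at gastruloid-only p300 regions (73.7%) and 2 at mESC-only ones, while of the 15973 mESC-only RXRα regions 2668 lay at mESC-only p300 regions (16.7%), 470 at gastruloid-only ones and 4509 at shared ones (28.2%), where p300 was in all 4 lists. The odds ratio of same against opposite class, which leaves the shared ones out, was 993 (95% interval 247 to 4002). This value does not show that the proteins change together. Within a cell type 85.8% (gastruloids) and 44.1% (mESCs) of RXRα regions were at p300 regions, and such overlap pairs regions of matching classes by itself. No value without joint change was computed to set beside it. The Dhrs3 region inside the gene was in both gastruloid-only classes, with p300 at 23.7 ± 2.84 (n = 2) and RXRα at folds of 19.2 and 9.63.

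Zeb2 and Sp5 divided the epithelial and EMT list unevenly. Among p300 regions that held only 1 of these factors, 39.9% held Zeb2 (3168 of 7938), but 22 of 26 did in the epithelial list (84.6%; median of random lists 42.3%; two-sided permutation, adjusted p = 0.0032), and 15 of 17 in endoderm and notochord (88.2%; adjusted p = 0.0336). Zeb2 represses epithelial genes such as Cdh1, but no p300 region of Cdh1 held Zeb2 or Sp5, so Cdh1 does not enter the tilt. The share was higher still in endoderm and notochord, so the tilt was not particular to the epithelial and EMT list. The call of Zeb2 over all epithelial p300 regions depended on the setting, as given above. The pair was compared inside 1 antibody, so a background common to HA precipitations would fall on both sides, but not evenly. Peaks of the first RXRα gastruloid replicate covered 72.1% of p300 regions held by Sp5 alone and 50.2% by Zeb2 alone. The comparison therefore does not set such a background aside. Zeb2 lists were longer than Sp5 lists in both replicates, 44310 against 19714 in the first and 12222 against 11932 in the second.

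All 3 factors met at 643 p300 regions, and 63.5% of these were at gene ends, against 6.11% of p300 regions with none. The count of 643 rests on the short second RXRα gastruloid list: with peaks of the first RXRα replicate alone it was 3684. Of the 16 lists only Hox genes were over-represented, with 6 of 92 p300 regions (6.52%, two-sided permutation, adjusted p = 0.0384). This call rests on those 6 regions and was made in the main setting only, without Hox genes drawn as runs of neighbours. The strongest of the 643 by p300 included regions near Sox13, Lhpp, Gtf3a, Ski, Hoxa4 and F11r. Signal common to all precipitations may produce such regions, as may true joint binding, and the first RXRα gastruloid replicate covered 80.2% of the distal and 86.9% of all p300 regions with both Sp5 and Zeb2.

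The genes with the most gastruloid-only p300 regions were Zfp608 (19, with 3 mESC-only) and Epha4 (18 and 6), followed by 7 genes with 16 each and 0 to 7 mESC-only regions. Arid5b led the mESC-only class (13, with 7 gastruloid-only), followed by Irf2bpl, Msi2, Tfap2c, Tns3 and Zc3h12a at 9 each. These counts were not corrected for the space around each gene, and genes in wide gene-poor stretches collect more regions.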
